A study of Mus musculus with 2 samples.

How the data were processed

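Single cells from the dorsal skin of female mice were measured in 2 libraries, 1 from wild-type (WT) mice and 1 from Chrna5 knockout mice, both treated with the vaseline base of a cream. Per the labels, the mice were 6 to 8 weeks old and the skin was taken on day 7. The skin was digested with collagenase, and live cells were sorted as SytoxBlue-negative. The labels name the strain as C57BL/6, with C57BL/6N in the breeding protocol and C57BL/6J in the extraction protocol. The extraction protocol also speaks of skin treated with imiquimod, whereas the sample labels, the series title and the design all name vaseline. The number of mice behind each library and the part of Chrna5 that was deleted are not given in the sources used here.

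The deposited matrices held UMI counts per gene and cell barcode, whole numbers with no normalization, per the file headers. The counts were made with Cell Ranger 3.0.2 against mm10, and Seurat 3.0 was named without a role, per the submitters' processing notes. Per the file headers, the Cell Ranger software carried a later version than these notes give. The filters applied before deposit are not stated in the sources used here. The lowest deposited barcode held 500 UMIs in the WT library and 501 in the knockout library. A total of 34 barcodes occurred in both libraries. Gene coordinates were taken from GENCODE vM21 for GRCm38 (mm10), counted from 1, and matched by Ensembl identifier.

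Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. This left 10160 of 10741 barcodes in the WT library and 9308 of 9696 in the knockout library. Doublets were scored in each library with the Scrublet method in scanpy 1.11.5, at an assumed doublet rate of 0.08. The thresholds that Scrublet chose, 0.735 for WT and 0.420 for the knockout, marked 0.0197% and 1.56% of cells, so the caller's own threshold had not worked for the WT library. A common score of 0.25 was therefore set after seeing the data, and it removed 494 WT cells (4.86%) and 467 knockout cells (5.02%). The kept cells numbered 9666 and 8841, with 127582029 and 114717152 UMIs.

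Both libraries were clustered together. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were taken without mitochondrial, ribosomal protein, haemoglobin, sex-linked and dissociation-stress genes. Then 30 principal components, 15 neighbours and the Leiden method in igraph 0.11.9 at resolution 1 gave 24 clusters. Fixed marker lists of 16 classes, divided into 24 subclasses, named each cluster by the highest mean of marker levels, each scaled to the highest cluster. At least 3 markers had to be found in 25% of the cluster's cells, and keratinocyte clusters were then compared among themselves for their subclass. Cluster 21, with a median of 1054.5 UMIs per cell, stayed unnamed because too few markers of its nearest keratinocyte subclass were found. Cluster 10 had no marker of its own class and a Langerhans cell marker, H2-M2, among its 10 leading genes. Clusters 4, 6, 9, 14 and 17 had no marker of their own subclass among their leading genes either, and cluster 6 had 1 of another subclass, so these names rest on marker levels alone. The keratinocyte pools are therefore given by cluster number: 1 to 10, 12, 14, 16 and 17 together, 6, 8, 9, 10, 12 and 17 as basal-like, 2, 3 and 4 as suprabasal-like, 5, 7 and 14 as outer root sheath-like, 1 as upper hair follicle-like and 16 as hair matrix-like. The other classes were cluster 0 (dermal papilla and sheath-like), 20 and 22 (fibroblast-like), 11 and 15 (T and innate lymphoid-like), 13 (melanocyte-like), 18 (Langerhans cell-like), 19 (pericyte-like) and 23 (skeletal muscle-like).

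Counts were summed over the cells of a class in each library and expressed as CPM, the counts scaled to a common total over all genes. The knockout CPM was divided by the WT CPM, and every ratio in the text is in that direction. Ratios carry exact conditional binomial 95% intervals, sums exact Poisson 95% intervals and shares exact Clopper-Pearson 95% intervals (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). A count of 0 was replaced by the floor of 3 counts over the class in that library. The ratio is then a bound set by that floor, and its interval can reach beyond it. The same floor held under the alternatives, so a value after thinning can be a bound nearer to 0. Classes with at least 100 cells in both libraries were compared, and a gene counted as measured with at least 20 UMIs over both libraries. Higher or lower means a ratio of at least 1.5 either way with an interval that leaves out 1. With 1 library per genotype there was no test across samples, and no p-value, standard error or count of changed genes was made from cells. The median log2 ratio over all measured genes lay within 0.1 of 0 in each compared class, and so did the shifts given by TMM and median-of-ratios factors.

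The named genes are the 6 with the highest and the 6 with the lowest ratio in each class with at least 200 cells in both libraries. They needed at least 50 UMIs over both libraries and, in the higher library, 50 CPM, a UMI in 5% of the cells and a CPM of at least 0.2 of that in the highest class, so that free RNA of another class was left out. Their intervals had to leave out 1. Mitochondrial, ribosomal protein, haemoglobin, sex-linked, immunoglobulin and T cell receptor segment genes, and genes with provisional names, were left out of this ranking. For each gene list, the 2 highest and the 2 lowest measured members were named in its classes, and Chrna5 was named in each class. A few genes that these rules named are not reported here, although the medians and counts of the gene lists include them.

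A total of 27 gene lists were described by the median log2 ratio of their measured members, with an interval from the order statistics of the members. Each median was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these 2 libraries. Lists with fewer than 5 measured members in a class got no median. The lists, the classes for each list, the marker genes, the cell filter, the clustering settings, the rule for named genes and 31 of the alternatives were chosen before the data were examined. Cells with a UMI of Mki67 or Top2a were counted after thinning each cell to 1000 UMIs and leaving out shallower cells.

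The comparison of class sums was tested on simulated data drawn from the pooled profile and the sizes of the real sums, with 200 genes moved by known folds. For the keratinocyte-like clusters, with 14613 genes, a fold of 0.333 was recovered for 100% of the moved genes, 0.5 for 92%, 2 for 100% and 3 for 100%. Of the unmoved genes, 0.604% were called. For the fibroblast-like class, with 9527 genes, the shares were 95.5%, 62.5%, 92% and 100%, with 2.20% of unmoved genes called. For the T and innate lymphoid-like class, with 9467 genes, they were 97.9%, 79.6%, 90% and 100%, with 2.00% called. For the dermal papilla-like class, with 11367 genes, they were 95.9%, 79.6%, 88% and 100%, with 1.74% called. Simulated lists of 25 genes moved by 0.667 lay at percentile 0 in each class. Unmoved simulated lists lay between percentile 1.43, in the upper hair follicle-like pool, and 92.7, in the fibroblast-like class, so percentiles inside that range also came up where nothing had been moved. The simulated counts held counting error only, without differences between mice and without genes that move together. Real lists can therefore lie outside that range, and more unmoved genes be called, without an effect of the genotype.

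The alternatives were another cell filter (1000 UMIs, 500 genes, 10% mitochondrial) or none, doublets kept, resolutions of 0.5 and 2, each library clustered alone, and shares without keratinocytes. For expression they were TMM factors (edgeR 4.0.16, R 4.3.3), median-of-ratios factors (DESeq2 1.42.0), CPM without mitochondrial, ribosomal and haemoglobin genes, the mean over cells of each cell's CPM, and 5% of each class's UMIs subtracted as free RNA. They also took in cells thinned to 1000 UMIs and minimums of 100 UMIs or none. A further 7 were added after seeing the data: Scrublet's own thresholds for shares, expression and lists, and, for expression and lists, clusters weighted alike in both libraries and pools without their most unevenly split clusters. Members of the mitochondrial, haemoglobin and surface keratin lists were not followed as single genes under the alternatives. Figures were drawn with matplotlib 3.10.9. Raw reads were not used here, so which exons the Chrna5 reads came from was not analysed here.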

Results

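Single-cell RNA from the dorsal skin of vaseline-treated female mice was compared between 1 wild-type (WT) library and 1 Chrna5 knockout library. The WT library held 10741 barcodes with 139673385 UMIs, a median of 12245 UMIs and 3064 genes per barcode, and the knockout library held 9696 barcodes with 125458721 UMIs and medians of 12223.5 and 3012. After filtering, 9666 and 8841 cells were kept. The labels name vaseline for both libraries, while the extraction protocol speaks of imiquimod-treated skin, and the values below are read under the vaseline labels. There were no replicates and so no replicate check, every difference below is between these 2 libraries rather than between genotypes, and all intervals cover counting error only. Ratios are knockout over WT, and coordinates are on GRCm38 (mm10) with GENCODE vM21.

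Chrna5, the targeted gene, which encodes the alpha 5 nicotinic receptor subunit (ENSMUSG00000035594, chromosome 9:54980880-55007779, plus strand), was nearly unmeasured in both libraries. Over all kept cells it had 11 UMIs (5.49 to 19.7) in the WT library and 2 (0.242 to 7.22) in the knockout library, a CPM ratio of 0.202 (0.0218 to 0.927). Over every barcode it had 13 and 3 UMIs. A UMI was found in 0.103% (0.0496 to 0.190) of WT cells and 0.0226% (0.00274 to 0.0817) of knockout cells, and in no cell of either library after thinning to 1000 UMIs. The dermal papilla-like class had 6 and 1 UMIs, in 1.03% and 0.197% of its cells, and the keratinocyte-like clusters had 5 and 1, of which the basal-like pool held 1 and 0 and the outer root sheath-like pool 1 and 1, while most of the WT UMIs of these clusters lay in the small hair matrix-like cluster. The suprabasal-like and upper hair follicle-like pools had none, nor had the fibroblast-like class, where the exact intervals of a count of 0 reach 2.39 and 2.51 CPM. No Chrna5 UMI was found among 759 WT and 666 knockout T and innate lymphoid-like cells at median depths of 2653 and 2746 UMIs. The sources used here do not say which part of the gene was deleted, and 3-prime tags outside a deletion check nothing about it.

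The measured genes next to Chrna5 on chromosome 9 were neither higher nor lower. Psma4, a proteasome subunit gene, had 214.8 and 198.7 CPM over all kept cells, a ratio of 0.925, and Ireb2, which regulates iron metabolism, had 20.9 and 19.4 CPM (0.929). Hykk had 88 and 84 UMIs, Chrnb4, a neighbouring nicotinic subunit gene, had 30 and 29, and Chrna3 had 0 and 5, too few to be measured. The fixed list named for the locus also holds Rasgrf1, Ctsh, Morf4l1 and Adamts7, which in the mouse lie far off on the same chromosome (from 9:89909908). Of these, Morf4l1 had 267 and 298 CPM, and Ctsh, a cathepsin gene, had 43.7 and 39.3 CPM, a log2 ratio that turned to 0.08 after thinning. This mixed list had a median log2 ratio of 0.10 (-0.15 to 0.28), with 0 genes higher, 0 lower and 8 neither, at percentile 90.9 of matched random lists. Both libraries had the transcripts of the labelled female sex. Xist, expressed from the inactive X chromosome, had 1172 and 1159 CPM (0.988) and Tsix had a ratio of 0.889. The Y-linked genes Ddx3y and Eif2s3y had 0 UMIs in both, Uty had 2 and 1, and Kdm5d had 0 and 1. Nnt, whose transcript is lower in the C57BL/6J substrain, had 69 and 68 UMIs.

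Among nicotinic and cholinergic genes over all kept cells, Slurp1, a secreted ligand of nicotinic receptors made by keratinocytes, was lower (0.444) and Chrm2, a muscarinic receptor gene, was higher (1.71). Chrna7 (0.657) and Slc5a7 (1.49), a choline transporter gene, were the next lowest and highest. Of the list, 1 gene was higher, 1 lower and 13 neither, with a median log2 ratio of 0.10 (-0.32 to 0.32) at percentile 94.3. Slurp1 was also the lowest in the keratinocyte-like clusters (0.421), ahead of Chrnb2 (0.756), and its log2 ratio over all kept cells was -1.17, with -1.87 after thinning and -0.41 as a mean over cells, and in these clusters -1.25, with -1.90 after thinning. Ache, acetylcholinesterase, was the highest there (1.47), ahead of Lypd6 (1.34), a receptor-modulating gene whose log2 ratio turned to -0.08 as a mean over cells. In these clusters 0 genes were higher, 1 lower and 7 neither, with a median of 0.13 (-1.25 to 0.56).

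Keratinocyte-like cells made up most of both libraries, and the clearest share differences lay within them. Suprabasal-like cells took a larger share of the knockout library, and the outer root sheath-like, upper hair follicle-like and hair matrix-like cells smaller shares. Melanocyte-like cells also took a smaller share. These are shares of SytoxBlue-negative live cells sorted after collagenase digestion, not of the skin. Keratinocyte-like cells together made up 78.2% (77.4 to 79.1) of kept WT cells and 79.8% (79.0 to 80.6) of kept knockout cells. Basal-like cells made up 42.0% (41.0 to 42.9) and 46.9% (45.9 to 48.0), suprabasal-like cells 14.0% (13.3 to 14.7) and 18.5% (17.7 to 19.3), a ratio of 1.32 (1.23 to 1.42). Outer root sheath-like cells made up 15.5% (14.8 to 16.2) and 10.4% (9.76 to 11.04), a ratio of 0.6696 (0.616 to 0.727), upper hair follicle-like cells 5.4004% (4.96 to 5.87) and 3.43% (3.06 to 3.83), a ratio of 0.635 (0.549 to 0.733), and hair matrix-like cells 1.42% (1.19 to 1.67) and 0.622% (0.469 to 0.809), a ratio of 0.439 (0.315 to 0.604). Melanocyte-like cells made up 1.91% (1.65 to 2.21) and 1.12% (0.911 to 1.36), a ratio of 0.585 (0.454 to 0.751), at median depths of 6497 and 3012 UMIs.

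Dermal papilla-like cells (6.05% and 5.75%), T and innate lymphoid-like cells (7.85% and 7.53%) and Langerhans cell-like cells (0.704% and 0.656%) had ratios of 0.949 (0.841 to 1.07), 0.959 (0.863 to 1.07) and 0.933 (0.645 to 1.34). The Langerhans cell-like cells had median depths of 3763.5 and 1087.5 UMIs, and their ratio ranged from 0.646 to 1.005 under the alternatives. Fibroblast-like cells made up 2.76% and 3.16%, a ratio of 1.14 (0.962 to 1.36), or 1.23 (1.04 to 1.46) without keratinocytes in the denominator. Pericyte-like cells numbered 13 and 4, skeletal muscle-like cells 32 and 34, and the unnamed cluster held 2.02% and 1.55%. No cluster was named as macrophages, endothelial cells, neutrophils, mast cells, B cells, Schwann cells, adipocytes or erythrocytes. Several clusters inside the pools were split unevenly: cluster 8 (325 and 1119 cells), 10 (1114 and 325), 5 (627 and 222), 4 (233 and 483), 2 (391 and 663), 6 (757 and 439), 15 (328 and 181), 20 (157 and 264) and 22 (110 and 15). In the suprabasal-like pool, clusters 2 and 4 were larger in the knockout library and cluster 3 smaller (725 and 487). In the outer root sheath-like pool, cluster 5 differed more than clusters 7 (626 and 523) and 14 (246 and 173), so this pool's gene ratios compare different cluster mixes. Cluster 10 was led by Tnip3, Ch25h, Epgn and Ccl20, cluster 4 by Id1 and C2cd4b, cluster 2 by Mt4 and Them5, cluster 3 by Prdm1 and cluster 6 by Nppb and Krt6a. Cluster 8 had the immediate early and stress genes Fos and Dnajb1 among its leading genes. The values of these genes in the pools that hold those clusters partly restate that split. Krt6a in the suprabasal-like pool cannot restate the split of cluster 6, which that pool lacks. Clusters 2, 3 and 4 of that pool were split unevenly too. The log2 ratio of Krt6a there was -1.56, and ranged from -1.58 to -1.09 under the alternatives, clusters weighted alike among them.

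**Figure D1:**
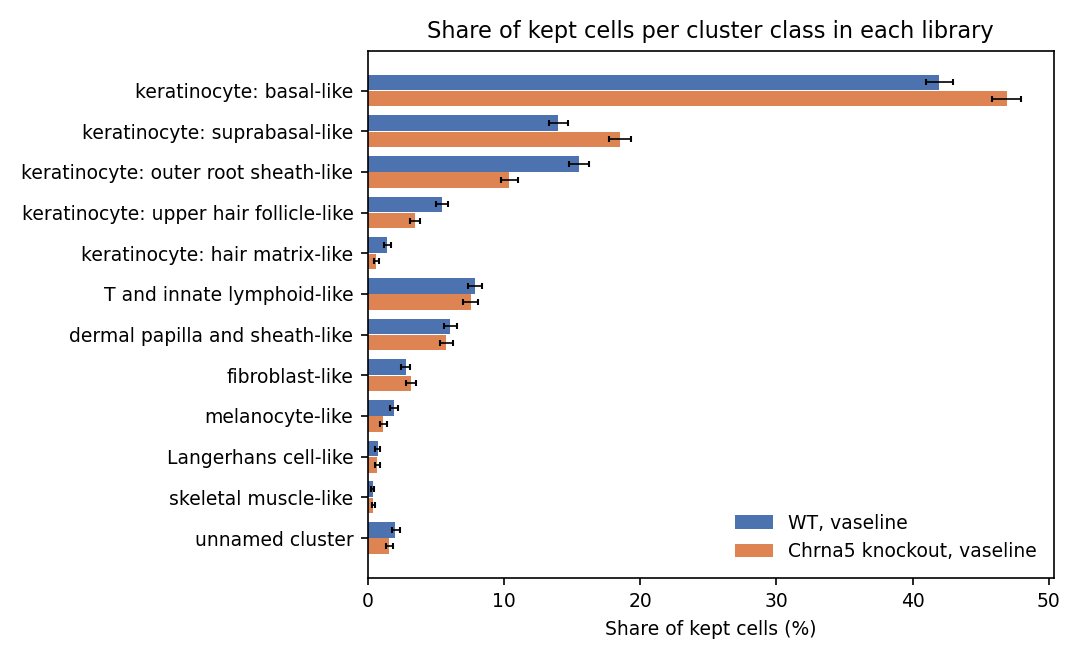
Share of kept cells in percent per class in the WT and the knockout library, with exact 95% counting intervals as bars. The outer root sheath-like share is 15.5% against 10.4%, and the suprabasal-like share 14.0% against 18.5%.

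In the keratinocyte-like clusters together, the interferon-induced gene Ifi27l2a, the chemokine gene Ccl20, the natriuretic peptide gene Nppb and Krt17, a keratin of hair follicles and activated epidermis, were lower in the knockout library. Epgn, which encodes an epidermal growth factor receptor ligand, and Ch25h, a cholesterol hydroxylase, were lower as well. Ptk2, which encodes focal adhesion kinase, the metallothionein gene Mt4, Id1, an inhibitor of differentiation, and the mitotic gene Cenpf were higher. Ifi27l2a had 271 CPM in WT and 34.7 in the knockout, a ratio of 0.128 (0.124 to 0.132), Ccl20 208 and 49.8 (0.239, 0.232 to 0.247), Nppb 227 and 59.8 (0.263, 0.256 to 0.2704) and Krt17 1685 and 713 (0.423, 0.420 to 0.427). Ch25h had 189 and 81.5 CPM (0.432) and Epgn 547 and 237 (0.433). Ptk2 had 22.6 and 62.1 CPM (2.75, 2.63 to 2.88), Mt4 166 and 349 (2.10, 2.06 to 2.14), Pcf11, a transcription termination factor gene, 58.2 and 106 (1.83), Smagp 44.3 and 75.8 (1.71), Id1 107 and 182 (1.70) and Cenpf 116 and 197 (1.70). The pool held 7562 and 7056 cells with median depths of 14414 and 14173 UMIs.

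Ccl20, Nppb and Epgn were lower in the basal-like and suprabasal-like pools alike. In the basal-like pool, Ccl20 had 204 and 39.3 CPM (0.192), Nppb 330 and 77.0 (0.234), Tnip3, a restrainer of NF-kB signalling, 51.1 and 14.5 (0.284), Epgn 742 and 284 (0.383), Ch25h 308 and 119 (0.388) and Fam43a 94.7 and 41.9 (0.442). Without the unevenly split clusters 8 and 10, the log2 ratio of Ccl20 was -1.79 instead of -2.38, and with clusters weighted alike that of Tnip3 was -1.15 instead of -1.81. Ptk2 (25.4 and 64.4 CPM, 2.53), the kinase gene Sgk1 (1.92), the interferon regulatory factor gene Irf1 (75.6 and 144 CPM, 1.91), Myc (74.6 and 138 CPM, 1.86), Smagp (1.85) and Serpinb7 (1.81) were higher there. In the suprabasal-like pool, Ccl20 (322 and 66.0 CPM, 0.205), Nppb (0.273), the injury-induced keratin gene Krt6a (485 and 164 CPM, 0.338), Cdk5r1 (0.340), Prdm1 (0.405), a transcriptional repressor gene, and Epgn (0.431) were lower. Ptk2 (10.97 and 52.5 CPM, 4.79), C2cd4b (2.25), Id1 (139 and 295 CPM, 2.13), Them5 (2.02), Pcf11 (1.91) and Sgk1 (1.87) were higher.

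In the outer root sheath-like pool, the natriuretic peptide gene Nppc (64.1 and 9.19 CPM, 0.143), Ifi27l2a (522 and 84.0 CPM, 0.161), the connexin gene Gjb2 (83.6 and 29.5 CPM, 0.353), and the chemokine genes Cxcl14 (815 and 303 CPM, 0.372) and Ccl2 (231 and 99.1 CPM, 0.428) were lower, as was Fam167a (0.376). Ptk2 (29.5 and 69.2 CPM, 2.35), Stfa1 (1.97), a stefin gene, Pcf11 (1.88), the clock gene Nr1d1 (1.80), Fam213a (1.74) and Sms (1.72), spermine synthase, were higher. In the upper hair follicle-like pool, Rgs4, a regulator of G protein signalling, was lower (83.7 and 2.83 CPM, 0.0339, 0.0174 to 0.0595), as were Ifi27l2a (356 and 26.5 CPM, 0.0744), the filaggrin gene Flg (140.4 and 30.002 CPM, 0.214), Crct1 (64.2 and 17.7 CPM, 0.276) and Ppif (0.390). Under the strict cell filter the log2 ratios in this pool were -0.05 for Flg and -0.26 for Crct1 instead of -2.23 and -1.86, and -3.08 for Ifi27l2a instead of -3.75, which was -2.86 after thinning. Ptk2 (9.17 and 57.9 CPM, 6.31), Pcf11 (1.99), Id1 (1.94), Dapl1 (1.82), the Notch target Hes1 (1.82) and the heat shock gene Hspa1a (1.79) were higher. After thinning, the log2 ratios in this pool were -3.69 for Rgs4 instead of -4.88, 1.79 for Ptk2 instead of 2.66 and 1.497 for Hes1 instead of 0.86, and that of Ppif was -0.74 as a mean over cells instead of -1.36.

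**Figure D2:**
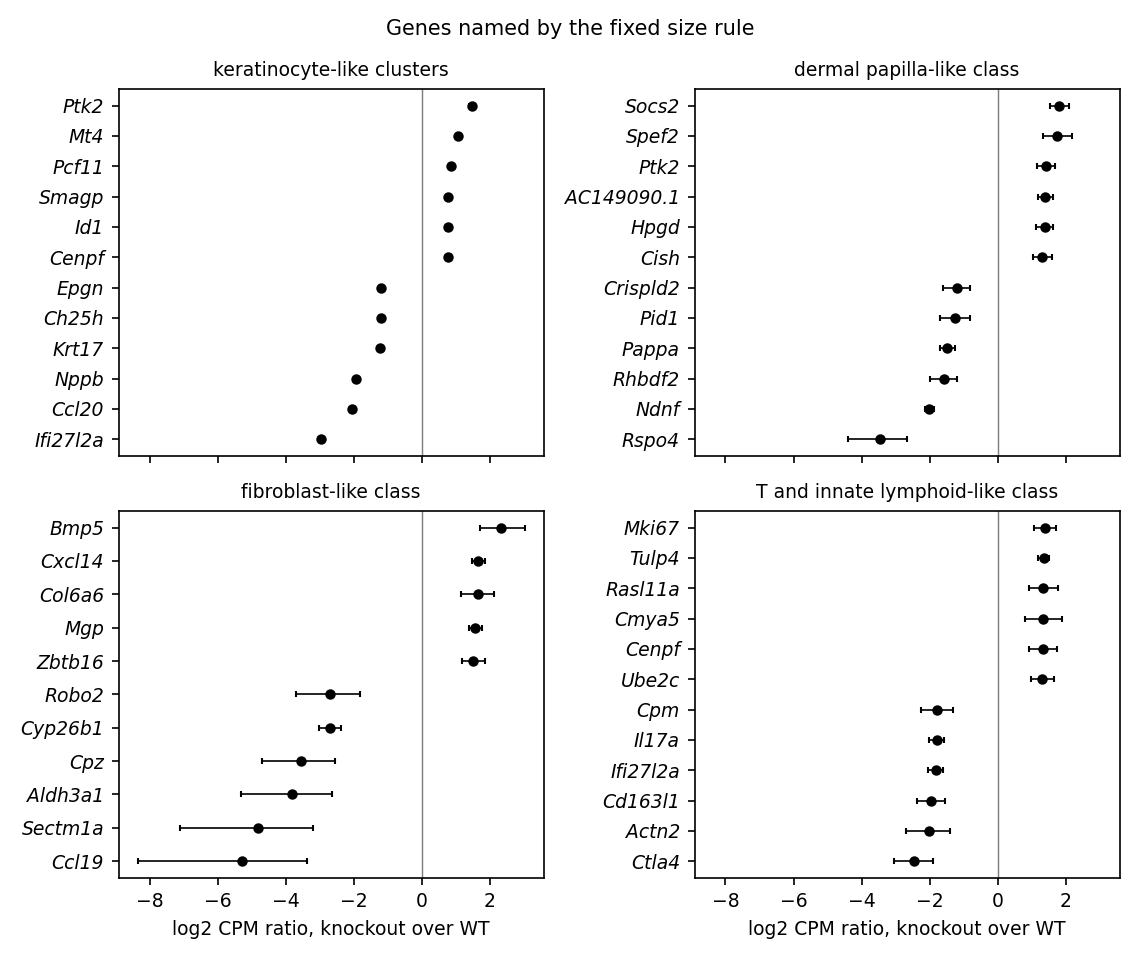
Log2 ratio of CPM, knockout over WT, for the genes named by the fixed rule in the keratinocyte-like, dermal papilla-like, fibroblast-like and T and innate lymphoid-like classes, with 95% counting intervals as bars. Ifi27l2a in keratinocyte-like clusters has a ratio of 0.128 and Ptk2 one of 2.75.

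Interferon-stimulated genes were lower across the keratinocyte-like clusters. Of the type I interferon response list, 1 gene was higher, 17 lower and 8 neither, with a median log2 ratio of -1.29 (-1.96 to -0.56) at percentile 0. Rtp4 (0.0382), Ifi44 (0.103), Ifit1 (0.123) and the ubiquitin-like modifier gene Isg15 (0.163) lay low, and Ifi211 (1.77) and Cmpk2 (1.65) lay highest. Inflammatory cytokine and chemokine genes had a median below 0 too, -0.60 (-1.03 to -0.21) at percentile 0, with 1 higher, 15 lower and 16 neither. The monocyte-attracting chemokine gene Ccl2 had 50.004 and 13.2 CPM (0.263), Ccl7 8.22 and 1.34 (0.163) and Ccl9 22 and 1 UMIs (0.0491, 0.00119 to 0.304), while Ccl5 (1.86) and Ccl4 (1.67) were the highest. Ccl9 had a log2 ratio of -1.62 under the strict cell filter instead of -4.35, and Rtp4 one of -2.31 after thinning and -5.95 with 5% free RNA subtracted instead of -4.71.

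Among genes of the IL-17 and psoriasis response, 2 were higher, 11 lower and 9 neither, with a median log2 ratio of -0.52 (-1.24 to 0.20) at percentile 0. The antiprotease gene Slpi (0.239) and Ccl20 (0.239) were the lowest. Stfa1 (1.63) and Sprr2d (1.56) were the highest, and the log2 ratio of Sprr2d turned to -0.05 after thinning. Cholesterol synthesis had 0 genes higher, 8 lower and 13 neither, with a median of -0.51 (-0.64 to -0.33) at percentile 0. Msmo1, a sterol oxidase gene, had a ratio of 0.576, while Mvk (1.11) and Fdps (0.840) lay highest. Antigen presentation had 0 higher, 6 lower and 14 neither, with a median of -0.36 (-0.60 to -0.25) at percentile 0. MHC class II genes were scarce in these clusters, with Cd74 at 6.29 and 3.87 CPM, against 20530 and 24304 in the Langerhans cell-like class. Lower values of such scarce genes, and of Ctss with 37 and 12 UMIs, need not come from keratinocytes. The cathepsin gene Ctss (0.350; log2 ratio -2.74 under the strict filter instead of -1.51) and the class I gene H2-Q7 (270 and 156 CPM, 0.578) were the lowest, and H2-D1 (0.978), whose direction turned with the scaling, and H2-Q4 (0.925) the highest.

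Hair cycle and Wnt genes had 1 higher, 14 lower and 13 neither, with a median log2 ratio of -0.61 (-0.97 to 0.08) at percentile 0, and a median of 0.02 with clusters weighted alike, beside the smaller outer root sheath-like and hair matrix-like shares. Krt35, a hair keratin gene (0.0960), and Fgf5, which ends hair growth (0.103), were the lowest, and the Wnt target Axin2 (1.69) and Tchh (1.27), trichohyalin, the highest. The log2 ratio of Fgf5 was -0.64 after thinning instead of -3.28. Epidermal differentiation had 3 higher, 6 lower and 18 neither, with a median of -0.20 (-0.53 to 0.17) at percentile 0.07, and of 0.045 after thinning. Flg (0.171) and the filaggrin-like gene Hrnr (0.351) were the lowest, and Krt2, a keratin of the upper layers (3.01), and Rptn, repetin (1.92), the highest. Of 1262 WT and 200 knockout Flg UMIs in these clusters, 1179 and 127 lay in the upper hair follicle-like pool. They came from 6.7% and 2.97% of that pool's cells, so the Flg ratio need not hold for the other keratinocyte-like cells. After thinning, the log2 ratios were -0.31 for Hrnr instead of -1.51 and 0.69 for Krt2 instead of 1.59, and that of Flg was -1.96 with clusters weighted alike and -1.88 as a mean over cells instead of -2.55.

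Most cell cycle genes were neither higher nor lower in the keratinocyte-like clusters, with 1 higher, 2 lower and 23 neither and a median log2 ratio of 0.23 (-0.09 to 0.32) at percentile 100. The mitotic genes Cenpf (1.70) and Mki67 (1.49) were the highest and the replication licensing genes Mcm2 (0.639) and Mcm3 (0.664) the lowest. Dissociation stress and immediate early genes had 2 higher, 1 lower and 32 neither, with a median of 0.17 (0.02 to 0.27) at percentile 100. The feedback inhibitor of cytokine signalling Socs3 had 222 and 373 CPM (1.68) and the chaperone gene Dnajb1 a ratio of 1.56, against Egr3 (0.617) and Ier3 (0.686). Nearer to 0 lay glycolysis and hypoxia (-0.09, -0.23 to -0.04; 0 higher, 2 lower, 22 neither; percentile 3.43), with the lactate exporter gene Slc16a3 (0.605) and Vegfa (0.652) lowest and Ankrd37 (1.23) and Pdk1 (1.11) highest. The unfolded protein response had a median of -0.15 (-0.37 to 0.02), with 0 higher, 1 lower and 19 neither, percentile 0.28, and Chac1 (0.588), Xbp1 (0.741), Herpud1 (1.498) and Dnajb9 (1.26) at its ends.

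The oxidative stress response had a median log2 ratio of -0.10 (-0.17 to 0.02) in these clusters, with 0 higher, 2 lower and 18 neither, percentile 5.62. Its cystine transporter gene Slc7a11 (0.520) and Gsta4 (0.533) were the lowest, and Txnrd1 (1.21) and Hmox1 (1.13) the highest. Adipogenic and lipid handling genes had a median of -0.08 (-0.32 to -0.02), with 0 higher, 2 lower and 18 neither, percentile 16.8, from Lpl (0.437), lipoprotein lipase, and Scd2 (0.654) to Agpat2 (1.07) and Apoe (1.06). Circadian clock genes had a median of 0.08 (-0.08 to 0.37), with 0 higher, 1 lower and 15 neither, percentile 95.2, from Bhlhe41 (0.554) and Per2 (0.756) to Nr1d2 (1.39) and Nr1d1 (1.32). After thinning, the log2 ratios were -1.71 for Slc7a11 instead of -0.94, -0.43 for Lpl instead of -1.20 (-1.89 with 5% free RNA subtracted) and -1.64 for Bhlhe41 instead of -0.85, and that of Pdk1 turned to -0.05, while that of Hmox1 turned to -0.07 as a mean over cells. Mitochondrially encoded genes had a median of -0.15 (-0.43 to 0.11) in the keratinocyte-like clusters, -0.08 in the basal-like, -0.03 in the suprabasal-like, -0.13 in the outer root sheath-like and -0.18 in the upper hair follicle-like pool. Surface keratins had medians of 0.05, -0.03, 0.03, 0.08 and 0.02 in the same order. The haemoglobin gene Hbb-bs had 89 and 18 UMIs in the keratinocyte-like clusters, 300 and 0 in the dermal papilla-like class, 6 and 64 in the T and innate lymphoid-like class, and 0 in both libraries in the fibroblast-like class.

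**Figure D3:**
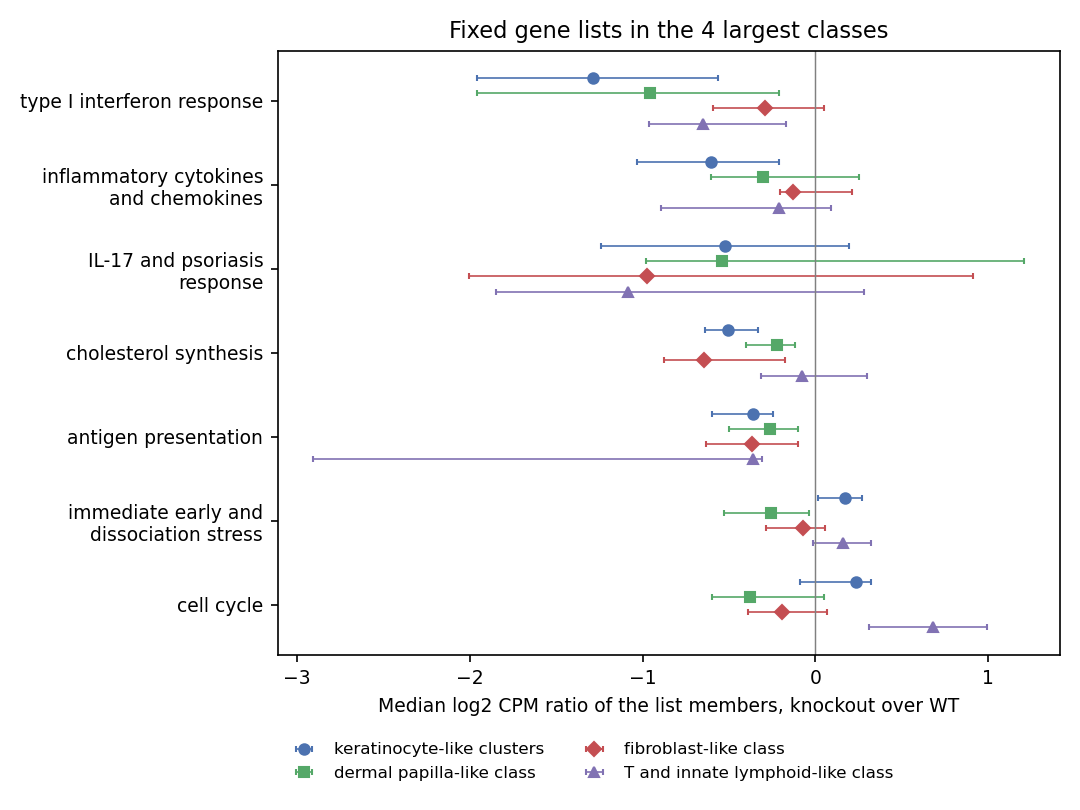
Median log2 ratio, knockout over WT, of 7 fixed gene lists in 4 classes, with the interval of the median over list members as bars. The interferon list lies at -1.29 in keratinocyte-like clusters, and the cell cycle list at 0.68 in T and innate lymphoid-like cells.

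Cells with a UMI of the proliferation genes Mki67 or Top2a took larger shares of the keratinocyte-like cells in the knockout library. After thinning to 1000 UMIs, they made up 17.3% (16.4 to 18.1) of WT and 20.8% (19.8 to 21.8) of knockout keratinocyte-like cells, with 38 shallower cells left out of each library, and 42.2% and 45.2% without thinning. In the basal-like pool they made up 22.6% (21.4 to 24.0) and 27.7% (26.3 to 29.1), in the outer root sheath-like pool 18.3% (16.3 to 20.3) and 24.8% (22.04 to 27.7), and in the suprabasal-like pool 2.17% and 3.05%. In the T and innate lymphoid-like class they made up 5.84% (4.14 to 7.95) and 9.93% (7.55 to 12.8). The dermal papilla-like class, taken as background, had 1.96% and 2.24%. With 2 UMIs of the whole cell cycle list as the mark, the ratio of shares turned to 0.956 in keratinocyte-like clusters, 0.984 in the basal-like pool and 0.871 in the T and innate lymphoid-like class, while it stayed above 1 in the outer root sheath-like and suprabasal-like pools. That mark changed the genes and the number of UMIs together.

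In the dermal papilla-like class, Rspo4, which encodes a Wnt agonist, Ndnf, a secreted growth factor gene, and Pappa, a protease gene of insulin-like growth factor signalling, were lower in the knockout library. Socs2 and Cish, feedback inhibitors of cytokine signalling, the prostaglandin-degrading gene Hpgd and Ptk2 were higher. Rspo4 had 54.6 and 4.91 CPM (0.0900, 0.0471 to 0.157), Ndnf 943 and 235 (0.249, 0.228 to 0.271), Rhbdf2 76.2 and 25.3 (0.332), Pappa 237 and 85.0 (0.358), Pid1 51.3 and 21.5 (0.419) and Crispld2 62.6 and 27.2 (0.434). Socs2 had 38.2 and 134 CPM (3.52, 2.89 to 4.30), Spef2 18.2 and 60.8 (3.34), Ptk2 49.2 and 130 (2.65), AC149090.1 68.7 and 181 (2.63), Hpgd 55.4 and 144 (2.59) and Cish 44.7 and 111 (2.49). After thinning, the log2 ratios were -2.04 for Crispld2 instead of -1.20, -4.76 for Rspo4 instead of -3.47 and -0.95 for Rhbdf2 instead of -1.59, and that of Crispld2 was -0.59 with doublets kept. The class held 585 and 508 cells at median depths of 6743 and 5347.5 UMIs. Mitochondrially encoded genes had a median of -0.45 (-0.60 to -0.01) here, with mt-Nd3 (0.344) and mt-Co3 (0.468) lowest, and surface keratins, taken as free RNA, 0.29 (-0.36 to 0.61), with -1.99 under the doublet caller's own thresholds and 1.98 with 5% free RNA subtracted.

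In the fibroblast-like class, the chemokine gene Ccl19, the retinoic acid-degrading gene Cyp26b1 and the aldehyde dehydrogenase gene Aldh3a1 were lower in the knockout library. Bmp5, a bone morphogenetic protein gene, the chemokine gene Cxcl14 and Mgp, matrix Gla protein, were higher. Ccl19 (ENSMUSG00000071005) had 52.6 and 1.36 CPM (0.0259, 0.00308 to 0.0966), Sectm1a 57.1 and 2.04 (0.0358), Aldh3a1 57.7 and 4.08 (0.0707), Cpz 71.4 and 6.13 (0.0858), Cyp26b1 392 and 60.6 (0.155, 0.122 to 0.193) and Robo2 52.6 and 8.17 (0.155). Bmp5 had 16.2 and 81.7 CPM (5.04, 3.25 to 8.09), Cxcl14 181 and 573 (3.17, 2.76 to 3.64), Col6a6 32.4 and 101 (3.11), Mgp 213 and 630.3 (2.96) and Zbtb16 70.1 and 199.4 (2.85). The class held 267 and 279 cells, with cluster 22, led by Col1a1 and Col1a2, split 110 to 15. Without cluster 22, the log2 ratio of Cyp26b1 turned from -2.69 to 0.78. Ccl19, Sectm1a, Aldh3a1 and Robo2 then had at most 3 UMIs in either library and got no ratio. Their WT UMIs thus lay nearly all in cluster 22. With clusters weighted alike, Robo2 lay at -0.26 instead of -2.69, Cpz at -1.69 instead of -3.54, Bmp5 at 1.62 instead of 2.33, Col6a6 at 0.95 instead of 1.63 and Zbtb16 at 0.83 instead of 1.51. Thinning put Bmp5 at 3.41, Col6a6 at 2.31 and Robo2 at -4.14, and Aldh3a1 lay at -1.70 with doublets kept instead of -3.82. After thinning, Ccl19 and Sectm1a lay at -2.27 instead of -5.27 and -4.81. These 2 values are set by the floor of 3 counts in the knockout library and are read as bounds, not as smaller differences.

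Collagen and matrix genes in the fibroblast-like class had 3 higher, 9 lower and 21 neither, with a median log2 ratio of -0.25 (-0.53 to 0.05) at percentile 0, and of 0.01 with clusters weighted alike. Fmod, fibromodulin (0.0723), and Col7a1, an anchoring fibril collagen (0.251), were the lowest, and Col14a1 (1.96) and Col5a3 (1.79) the highest. With clusters weighted alike, the log2 ratios were -1.42 for Fmod instead of -3.79 and -0.28 for Col7a1 instead of -1.997 (-3.75 after thinning), and without cluster 22 that of Col5a3 was 0.20 instead of 0.84. The interferon list had 3 higher, 6 lower and 15 neither, with a median of -0.29 (-0.59 to 0.05) at percentile 0 and of -0.63 with clusters weighted alike, from Isg15 (0.227) and Ifit3b (0.294) to Ifi211 (2.19; log2 ratio 0.46 with clusters weighted alike instead of 1.13) and Ifi203 (1.81). Inflammatory genes had 3 higher, 2 lower and 20 neither, with a median of -0.13 (-0.20 to 0.21) at percentile 1.7, and of 0.14 after thinning. Ccl8 (130 and 41.5 CPM, 0.318) was low beside Ccl19, and its log2 ratio turned to 0.49 without cluster 22. The neutrophil-attracting chemokine gene Cxcl1 was high beside Cxcl14, at 1136 and 2173 CPM (1.91), and had a log2 ratio of 0.27 with clusters weighted alike instead of 0.94. Mitochondrially encoded genes were lower in this class, with a median of -0.83 (-1.02 to -0.61) and 0 higher, 11 lower and 2 neither, mt-Nd3 (0.194) and mt-Co3 (0.405) lowest. Surface keratins had a median of 0.40 (-0.14 to 1.42), and of -0.78 with the doublet caller's own thresholds.

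Matrix remodelling genes in the fibroblast-like class had a median log2 ratio of -0.10 (-0.23 to 0.16), with 2 higher, 2 lower and 17 neither, percentile 6.41, from the matrix metalloproteinase gene Mmp27 (0.555) to Plau (1.96) and Mmp3 (1.59). Adipogenic genes had a median of -0.11 (-0.19 to 0.24), with 1 higher, 0 lower and 15 neither, percentile 7.76, from Scd2 (0.701) and Elovl6 (0.734) to Lpl (1.87) and Cebpa (1.35). Stress and immediate early genes had a median of -0.07 (-0.29 to 0.06), with 0 higher, 6 lower and 29 neither, percentile 7.06, from Hspa1a (0.507) and Dusp1 (0.527) to Socs3 (1.36) and Dnajb1 (1.34). Glycolysis and hypoxia had a median of 0.03, with 1 higher, 1 lower and 18 neither, percentile 44.8, from Pfkl (0.525) and Ndrg1 (0.558) to the vasodilator gene Adm (2.59) and Hk2 (1.43). The unfolded protein response had a median of -0.08, with 0 higher, 0 lower and 18 neither, percentile 9.93, with Manf (0.752) and Canx (0.802) low and Sdf2l1 (1.42) and Dnajc3 (1.13) high. The oxidative stress response lay at 0.02, with 1 higher, 1 lower and 14 neither, percentile 39.9, with Hmox1 (0.461) and Cat (0.793) low and Gclc (1.65) and Gstm1 (1.43) high. The circadian clock lay at -0.07, with 1 higher, 1 lower and 12 neither, percentile 23.1, with Bhlhe41 (0.450) and Cry1 (0.620) low and Nr1d1 (1.90) and Per3 (1.37) high. The medians of these lists turned under alternatives: adipogenic genes lay at 0.41 and the clock at 0.11 after thinning, and with the doublet caller's own thresholds matrix remodelling lay at 0.25, glycolysis at -0.19 and the unfolded protein response at 0.07, while the oxidative stress response lay at -0.07 with clusters weighted alike. Several members depended on the split of clusters. With clusters weighted alike, the log2 ratios turned to 0.54 for Bhlhe41, 0.31 for Pfkl, 0.19 for Scd2 and -0.04 for Gstm1, and were 2.46 for Nr1d1 instead of 0.92 and 0.27 for Plau instead of 0.97. Thinning turned Mmp3 to -0.15 and Sdf2l1 to -0.86 and put Cry1 at -2.64 instead of -0.69, Ndrg1 turned to 0.09 without cluster 22, and Hk2 turned to -0.04 as a mean over cells.

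In the T and innate lymphoid-like class, Il17a, the cytokine gene of type 17 cells, Ctla4, an inhibitory receptor gene, Cd163l1, a marker of dermal gamma-delta T cells, and Ifi27l2a were lower in the knockout library. The proliferation genes Mki67, Cenpf and Ube2c were higher. Ctla4 had 89.8 and 16.5 CPM (0.183, 0.122 to 0.268), Actn2 54.1 and 13.4 (0.247), Cd163l1 120 and 30.9 (0.258, 0.191 to 0.342), Ifi27l2a 404 and 114 (0.283), Il17a 349 and 100.3 (0.287, 0.244 to 0.337) and Cpm 86.1 and 25.2 (0.293). Mki67 had 55.1 and 143 CPM (2.60, 2.09 to 3.25), Tulp4 196 and 500.1 (2.55), Rasl11a 30.1 and 76.2 (2.53), Cmya5 20.8 and 52.5 (2.52), Cenpf 33.3 and 83.9 (2.52) and Ube2c 50.4 and 125 (2.48). The class held clusters 11 (431 and 485 cells) and 15 (328 and 181 cells). With these clusters weighted alike, the log2 ratios were -0.93 for Il17a instead of -1.80, -1.58 for Ctla4 instead of -2.45, -1.15 for Actn2 instead of -2.02, -0.91 for Cpm instead of -1.77 and -1.03 for Ifi27l2a instead of -1.82, which without cluster 15 was -3.22. Without cluster 15, that of Cd163l1 turned from -1.96 to 0.26. With the doublet caller's own thresholds, Cenpf lay at 0.71 instead of 1.33 and Ube2c at 0.60 instead of 1.31, and thinning put Ube2c at 0.47 and Rasl11a at 2.19 instead of 1.34.

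An Il17a UMI was found in 9.62% (7.61 to 11.9) of WT and 3.00% (1.84 to 4.60) of knockout T and innate lymphoid-like cells, and in 7.73% (5.77 to 10.1) and 1.84% (0.885 to 3.35) after thinning to 1000 UMIs, which left out 125 and 122 shallower cells. In keratinocyte-like cells, which should lack Il17a, the shares were 0.370% and 0.0567%, or 0.0266% and 0 after thinning. A Cd163l1 UMI was found in 12.9% (10.6 to 15.5) and 4.35% (2.94 to 6.19) of the T and innate lymphoid-like cells, against 0.185% and 0.0709% of keratinocyte-like cells.

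The IL-23 and IL-17 cytokine axis had 1 gene higher, 9 lower and 4 neither in this class, with a median log2 ratio of -1.28 (-1.92 to 0.09) at percentile 0, and of -0.56 with clusters weighted alike. The cytokine genes Il1b (197 and 48.9 CPM, 0.249) and Il22 (61.5 and 15.4 CPM, 0.251) were the lowest, and Ifng (30.1 and 74.1 CPM, 2.46) and Il6 (1.88) the highest. Over all kept cells the same list had 1 higher, 9 lower and 8 neither, with a median of -0.57 (-1.08 to 0.02) at percentile 0, from Il22 (0.254) and Il17a (0.283) to Ifng (2.45) and Il12b (1.71). T cell activation and cytotoxicity had 6 higher, 6 lower and 14 neither, with a median of 0.16 (-0.39 to 0.44) at percentile 93.9, and of -0.08 without cluster 15. The regulatory T cell gene Foxp3 had 38 and 0 UMIs, a ratio of 0.0878 against the floor for a count of 0, with an interval up to 0.113. Its log2 ratio against the floor was -1.65 after thinning instead of -3.51, as the floor stays while the WT count falls. The type 2 cytokine gene Il5 had 11.1 and 102 CPM (9.17, 5.99 to 14.7) and was the highest, with Ifng next. With clusters weighted alike, the log2 ratios were 4.07 for Il5 instead of 3.20, 2.16 for Ifng instead of 1.3006 and -1.15 for Il1b instead of -2.01, which was -2.76 under the strict cell filter.

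Cell cycle genes in the T and innate lymphoid-like class had 13 higher, 0 lower and 13 neither, with a median log2 ratio of 0.68 (0.31 to 1.00) at percentile 100, and of 0.31 with the doublet caller's own thresholds. Mki67 and Cenpf were the highest, and Cenpa (0.960) and Mcm2 (0.986) the lowest. Stress and immediate early genes had a median of 0.16 (-0.02 to 0.32), with 2 higher, 3 lower and 30 neither, percentile 95.6, from Egr2 (0.245) and Hspb1 (0.530) to Fos (1.70) and Klf4 (1.66), with 0.36 for the median with clusters weighted alike and -0.91 for the log2 ratio of Egr2 without cluster 15 instead of -2.03. Surface keratins, taken as free RNA, had a median of -0.60 (-1.06 to 0.11) in this class, Krt14 at 1144 and 547 CPM and Krt17 at 173 and 60.2. Mitochondrially encoded genes had a median of -0.18. MHC class II genes, which T cells of mice hardly express, were lower as well, Cd74 at 961 and 78.7 CPM and H2-Ab1 at 547 and 34.0. Nearly all of these lay in cluster 15, with Cd74 at 2053 and 254 CPM there and at 21.5 and 19.3 in cluster 11, so transcripts of antigen-presenting cells differed within that cluster beside the cytokine genes.

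Ptk2 and Wdfy1, an endosomal adaptor gene, were higher, and Isg15, Ifi27l2a, Mid1 and Rpl29 lower, in every compared pool. Of 7581 genes measured in all 7 pools, 2 were higher and 9 lower in each, a set chosen after the values were seen. Ptk2 (chromosome 15:73205102-73423280) had 37.6 and 72.2 CPM in the fibroblast-like class (1.92) and 8.79 and 44.8 in the T and innate lymphoid-like class (5.09). Wdfy1 (chromosome 1:79702262-79776143) had 1.93 and 8.86 CPM in the basal-like pool. Gm47283 (chromosome Y:90784738-90816464) had 208 and 3.49 CPM there, and Mid1 (chromosome X:169685199-170005736), which spans the pseudoautosomal boundary, 17.8 and 2.63. The ribosomal protein gene Rpl29 (chromosome 9:106429454-106431568) had 1873 and 1040 CPM and mt-Nd3, a complex I gene, 251 and 110. The melanocyte genes Mlana, Pmel and Tyrp1 were the others, with Pmel at 29.6 and 13.3 CPM in the basal-like pool, beside the smaller melanocyte-like share. Although Gm47283 is placed on chromosome Y, it was not read as a sign of male cells. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had at most 2 UMIs in either library. Whether Gm47283 lies in the part that X and Y share was not analysed here.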

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

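The digestion test below was chosen only after the result was seen, and the test of the cluster mix rests on an alternative added after seeing the data, with its bounds set before its own value was seen.

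Dissociation stress and immediate early genes went opposite ways in a pair of classes under the same comparison, which is why they stand here. Their median log2 ratio was 0.17 in the keratinocyte-like clusters and -0.26 in the dermal papilla-like class, and the difference between these classes was not tested. In the dermal papilla-like class, 0 genes were higher, 10 lower and 25 neither, with Egr3 (0.471), Egr1 (0.512) and Dnajb1 (0.540) among the lowest.

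A longer or harsher digestion of the knockout skin could raise such genes, and would then raise them in every class, but the upper bound of the median in the dermal papilla-like class was -0.0386. Since this value is part of what put the list here, it argues only against a digestion that raised these genes in every class. A different mix of keratinocyte clusters could also move the list, as cluster 8 (325 WT and 1119 knockout cells) had Fos and Dnajb1 among its leading genes. With clusters weighted alike, however, the median of the list in keratinocytes was 0.19, which argues against a different mix too. An effect of the genotype on these genes was not tested and stays open, as does a digestion that acted on the epidermis and the dermis unequally.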

How the results depend on the processing

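No paired analysis was possible because each genotype had 1 library. Of the values recomputed under the alternatives, 595 list medians, 81 share ratios, 14 cycling ratios and both Chrna5 values stayed within their intervals. For single genes, 2182 of 2653 did so, 451 moved, 93 of them by more than 1.5 times, and 20 with an interval that left out 0 turned direction. Of the 2182, 179 came from the minimum of 100 UMIs and 214 from no minimum. These settings leave a single gene's ratio unchanged by construction, so they say nothing about stability. For the changed values given below the cause was not tested. The doublet caller's own thresholds, clusters weighted alike and pools without unevenly split clusters were chosen after seeing the data. TMM and DESeq2 factors moved the log2 ratios of a class by at most 0.07.

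With each library clustered alone, share ratios were 0.987 for keratinocyte-like, 1.12 for suprabasal-like and 0.535 for upper hair follicle-like cells. Under the strict cell filter they were 0.452 for melanocyte-like and 0.543 for upper hair follicle-like cells. Without thinning, the cycling ratio was 1.07 in keratinocyte-like and 1.06 in basal-like cells, and with 2 UMIs of the whole list 0.956 and 0.984, with 1.04 in outer root sheath-like and 0.871 in T and innate lymphoid-like cells.

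After thinning to 1000 UMIs, list medians were 0.36 for the mixed list of chromosome 9 genes, 0.44 for nicotinic genes over all cells, 0.41 for fibroblast adipogenic genes, and for mitochondrial genes -0.58 in fibroblasts and 0.10 in outer root sheath-like cells (0.11 as a mean over cells). With the doublet caller's own thresholds they were 0.31 for the T cell cycle list, 0.25 for fibroblast matrix remodelling, -0.19 for fibroblast glycolysis, and for surface keratins -1.99 in dermal papilla-like, -0.78 in fibroblast-like and -0.0812 in outer root sheath-like cells. With clusters weighted alike they were -0.63 for fibroblast interferon genes, 0.36 for T stress genes and -0.51 for fibroblast mitochondrial genes, which lay at -0.47 without cluster 22. With 5% free RNA subtracted, surface keratins lay at 1.98 in dermal papilla-like and -1.48 in T and innate lymphoid-like cells.

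Log2 ratios that turned were, without unevenly split clusters, Cyp26b1 0.78, Ccl8 0.49 and Ndrg1 0.0918 in fibroblasts and Cd163l1 0.26 in T cells. After thinning they were Ctsh 0.0836 and Xist 0.0130 over all cells, Sprr2d -0.0516 and Pdk1 -0.0467 in keratinocytes and Mmp3 -0.15 in fibroblasts. As a mean over cells they were Ctsh 0.0115, Xist 0.00941, Lypd6 -0.0790, H2-D1 0.00728 and Hk2 -0.0403. Xist lay at 0.0313 with TMM and 0.0343 with DESeq2 factors, and H2-D1 at 0.0028 with TMM. With clusters weighted alike, Scd2 lay at 0.19, Gstm1 at -0.0424 and Bhlhe41 at 0.54 in fibroblasts. Pfkl (0.31) and Sdf2l1 (-0.86) in fibroblasts and Hmox1 in keratinocytes, whose intervals held 0, changed sign as well and count among those that moved.

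The keratinocyte interferon median ranged from -1.41 to -1.07 over all alternatives, the IL-17 and psoriasis median from -0.59 to -0.17, and the T cytokine axis from -1.78 to -0.56. Medians on both sides of 0 were those of keratinocyte epidermal differentiation (-0.21 to 0.045), keratinocyte hair cycle (-0.69 to 0.02), fibroblast collagens (-0.32 to 0.01) and T activation (-0.08 to 0.28), among others. For Chrna5, subtracting free RNA leaves the ratio unchanged by construction, and thinning left no UMI.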

Other observations

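For the patterns weighed below, the bounds for Il17a in Cd163l1 cells and for the cluster mix were set before those values were seen, the latter on an alternative added after seeing the data. The other scalings were chosen before the data were examined, but their bounds, and all other tests, only after the result was seen.

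Interferon-stimulated genes were also lower outside the classes fixed for that list. In the dermal papilla-like class 0 were higher, 8 lower and 6 neither, with a median log2 ratio of -0.96 (-1.96 to -0.21) and Ifi27l2a (0.126), Oasl2 (0.342) and the membrane restriction factor gene Bst2 (63.7 and 29.8 CPM, 0.469) low. Ifi27l2a had 50.8 and 6.42 CPM there, against 271 and 34.7 in keratinocyte-like clusters. Free RNA was not tested for these genes outside the keratinocyte-like clusters. In the T and innate lymphoid-like class 1 was higher, 9 lower and 7 neither, with a median of -0.65 (-0.96 to -0.17), Irf7 (0.541) low and Rsad2 (2.53) high. Cholesterol synthesis genes had a median below 0 in the fibroblast-like class as well, -0.64 (-0.87 to -0.17), with 1 higher, 8 lower and 10 neither. Fdft1 (0.362), Cyp51 (0.470) and Hmgcs1 (104 and 57.2 CPM, 0.551) were low and Hsd17b7 (2.31) high. The cholesterol synthesis genes were not followed under the alternatives in this class, whose clusters were split unevenly. In the dermal papilla-like class they had 0 higher, 3 lower and 18 neither, a median of -0.23 (-0.40 to -0.12), and Hmgcs1 at 356 and 199.4 CPM (0.560).

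No macrophage or endothelial cluster was found, so their lists were read over all kept cells. Keratinocyte-like cells made up 78.2% and 79.8% of these, so the values need not come from macrophages or endothelial cells. Resident macrophage genes had 4 higher, 5 lower and 6 neither, with a median log2 ratio of -0.29 (-1.07 to 1.21) at percentile 6.8, from the lectin gene Cd209d (147 and 7 UMIs, 0.0530) and Mrc1 (0.358) to Pf4 (4.13) and the type 2 marker Retnla (28 and 306 UMIs, 12.2, 8.24 to 18.6). Monocyte-derived macrophage genes had 0 higher, 6 lower and 8 neither, with a median of -0.26 (-1.08 to 0.09) at percentile 2.64, Ly6c2 (0.373), Spp1 (0.532) and Thbs1 (897 and 547 CPM, 0.610) low. Endothelial activation genes had 1 higher, 3 lower and 14 neither, with a median of -0.25 (-0.50 to 0.02) at percentile 5.75. The tip cell gene Esm1 (38 and 0 UMIs, 0.0878 against the floor for a count of 0) and Angpt2 (0.398) were low and Tek (1.98) high.

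The lower interferon genes could come from free RNA, from the scaling, from the mix of clusters or from the exposure of single mice. Free RNA from another class found here would bring that class's markers along, but to hold their WT excess, keratinocytes would need a share of a source class's level at least 223 times the median share of its markers seen in them (for fibroblasts, 9.76% against 0.0438%). Under 5 other scalings the keratinocyte median stayed between -1.28 and -1.07, and with clusters weighted alike it was -1.11. For the keratinocyte-like clusters these tests argue against all 3, apart from free RNA of cell types not found here. The exposure or batch of single mice and the genotype cannot be told apart with 1 library per genotype.

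Ptk2, higher in every class, could sit on a stretch of chromosome carried along with the knockout, but it lies on chromosome 15 and Chrna5 on chromosome 9. On chromosome 9 lay 1 of the genes that moved alike (9.09%) and 432 of the 7581 measured genes (5.70%). With 1 gene, these shares cannot be told apart. Libraries from different C57BL/6 substrains might differ at it, but Nnt had a ratio of 1.10 (0.772 to 1.55), which argues only against a wholly C57BL/6J library set beside a wholly C57BL/6N library. Gm47283, Mid1 and Wdfy1, on chromosomes Y, X and 1, also differed several-fold in every pool, so a difference in strain background, on chromosome 15 or elsewhere, stays open. Mid1 spans the pseudoautosomal boundary, so it and Gm47283 need not be separate loci. Free RNA would bring the source's markers along, but the share of a source's Ptk2 level needed was at least 5.74 times the share of its markers (55.6% against 9.68% for keratinocyte RNA in fibroblasts). An effect of the genotype was not tested and stays open.

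A further hypothesis was that Il17a was lower because fewer cells expressed Cd163l1, a marker of dermal gamma-delta T cells. Such cells numbered 98 in the WT library and 29 in the knockout library, and among them Il17a per UMI had a ratio of 0.599 (0.488 to 0.730). The value lay below the range set for alike levels, from 0.67, while its upper bound lay above it. By these bounds the test cannot tell whether fewer such cells alone account for the lower Il17a. Both parts were lower in the knockout library. Such cells made up 12.9% (10.6 to 15.5) and 4.35% (2.94 to 6.19) of the class, and the interval of the Il17a ratio among them left out 1. These intervals cover counting error only. That of the Il17a ratio takes 621 WT and 118 knockout UMIs as independent, although they came from at most 98 and 29 cells. The spread between cells is not covered, so the lower Il17a among such cells is a value of these libraries only.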
